A study of Mus musculus with 8 samples.

How the data were processed

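Chromatin immunoprecipitation with sequencing (ChIP-seq) of EBF1 and of Brg1 was measured in mouse pro-B cells transformed by A-MuLV, the Abelson murine leukaemia virus. The series holds 8 samples, of which 4 are immunoprecipitations and 4 are inputs. Each immunoprecipitation came with 1 peak list, and the inputs themselves were not analysed here. Samples were grouped by the genotype, treatment and antibody given in their labels, which left 1 library per group and no replicate. EBF1 was precipitated from the EBF1-dTAG_C line with 4 µg of antibody after fixation for 10 min in 1% formaldehyde, per the labels' protocols. Brg1 was precipitated from the EBF1-dTAG_N line with 0.5 µg of antibody after EGS and then 15 min in 1% formaldehyde. Cells received dTAG-13 at 0.5 µM for 6 h. For the controls the labels differ, since the treatment label and protocol give 6 h of DMSO and the titles give 0 h. The treatment label was used, and whether these cells were held in DMSO for 6 h stays unsettled.

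Per the submitters' processing notes, the tools were Bowtie2 2.3.5.1, SAMtools 1.10, deepTools 3.3.2 and MACS2 2.2.7.1, and the builds named are GRCm38 and mm10. Read filters, peak-calling settings and the control used for each call are not given in the sources used here. Peak names in the deposited lists run without gaps and carry 1 library's name per list, so peaks were called per library and not on pooled libraries. In each deposited list, the authors' fold enrichment of a peak is a linear ratio of the fragment pileup at the summit plus 1 to the local background plus 1. The authors' p and q values are deposited as −log10 values, the lowest −log10 q being 1.46, 7.57, 1.58 and 1.30 in the EBF1 DMSO, EBF1 dTAG-13, Brg1 DMSO and Brg1 dTAG-13 lists. The deposited score is the whole-number part of 10 times the −log10 q, and the last column of the deposited lists, another kind of value, is the distance of the summit from the start of the peak. These values are the authors'. They were used to rank, describe, filter, group or compare peaks within their own list. Fold enrichment and p also served to recover fragments and backgrounds, and those backgrounds were compared between lists.

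Library totals are not given in the sources used here, so the relative depth was recovered from the peaks. MACS2 computes fold enrichment as pileup plus 1 over background plus 1, and p from a Poisson distribution with that background. Solving both for each peak gave a whole number of fragments at the summit, within 0.02, for 100% of the peaks of every list. For the EBF1 lists this needed a scaling of the immunoprecipitation by 0.863 in DMSO and 0.818 after dTAG-13, and no scaling for Brg1. The lowest local background in a list was taken as the genome-wide background of that library, in fragments per base. For EBF1 it stands on the scaled-down scale, whereas fragments at summits are given unscaled. Peaks whose local background exceeded 5 times this lowest value are called high-background peaks. That definition was made after the data had been examined. The depth limits precision in that the median summit rested on 26 fragments in the EBF1 DMSO list, 35 in EBF1 dTAG-13, 13 in Brg1 DMSO and 18 in Brg1 dTAG-13.

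Peaks were compared by overlap of at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. No p-value was computed between conditions. The overlap of EBF1 and Brg1 peaks was set beside 10000 random placements of the EBF1 peaks on their own chromosomes, with a one-sided permutation p. Odds ratios over peaks were tested with Fisher's exact test, two-sided, and describe these lists and not the conditions. Summits were placed against the gene bounds of an annotation of GRCm38.p6, the build of the lists. That table gives neither strand nor exons, so distances to either end of a protein-coding gene replaced the planned distances to start sites, and exons and introns were not told apart. A summit was assigned to the protein-coding gene whose body held it, and otherwise to the gene with the nearest bound within 100 kb. No genome sequence was used, so the planned searches for the EBF1 motif and for other motifs at summits were not run.

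For the gene lists, the number of members with an assigned peak was set beside 10000 random lists of the same size, matched in 20 classes on the length of the region from which a gene can draw peaks. The one-sided permutation p was adjusted by Benjamini-Hochberg over 30 tests of 10 lists in 3 peak lists, and 0.05 was the threshold. All 218 symbols were found in the annotation, and 9 of them stand in more than 1 list. The lists were EBF1 and early B-lineage genes (25), B-lineage transcription factors (27), pre-B cell receptor signalling (25), proliferation and survival (28), BAF complex subunits (25), integrated stress and heat shock (20), T-cell genes (21), myeloid genes (20), erythroid and megakaryocyte genes (16) and neuronal genes (20). The last 4 stand for other cell types. The gene lists, the rule for naming and most, but not all, of the tests and alternatives were fixed before the data were examined.

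Genes and sites are named by a fixed rule. It takes the 15 peaks of each list highest by −log10 q, every peak of a list of 10 or fewer, and every peak found in both EBF1 lists. It adds the 10 highest EBF1 peaks for each pattern of Brg1 overlap (both conditions, DMSO only, dTAG-13 only), and up to 6 members with a peak from each gene list. Where a sentence counts a list's members, further members may be named. Some items that the rule takes are not reported here. The chromosome 5 stretch, the high-background positions, the antigen receptor loci and chromosome X were singled out after their values had been seen.

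Alternatives were a −log10 q of at least 5 or 10, a fold enrichment of at least 5, numbered chromosomes and X alone, reciprocal overlap of 50%, summits within 250 bp, intervals within 1 kb, a dTAG-13 Brg1 list shortened to the DMSO length by rank, shifts of 10 to 100 kb in place of random placement, gene bounds within 2.5 kb or of any gene, genes within 20 kb, and random lists without matching. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The steps were tested on simulated data. For the EBF1 and dTAG-13 Brg1 lists, all 60 overlaps planted among 312 sites were found, and 1 of 100 random site lists gave a p under 0.05. Of 200 random gene lists, 4 gave a p under 0.05. The fragment recovery returned 300 of 300 simulated peaks without scaling and 298 of 298 with it.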

Results

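ChIP-seq was used to map EBF1, a transcription factor required for B-cell development, and Brg1, the ATPase of the BAF chromatin remodelling complex encoded by Smarca4. The cells were A-MuLV-transformed pro-B cells, early B-lineage cells grown in culture, in which a tagged EBF1 took the place of the endogenous protein. The dTAG is a degron, and the small molecule dTAG-13 directs a protein that carries it to degradation. EBF1 was mapped in the EBF1-dTAG_C line and Brg1 in the EBF1-dTAG_N line, each after 6 h with 0.5 µM dTAG-13 and in a DMSO control, which the labels give both as 6 h of DMSO and as 0 h. There was 1 library per group, so no difference between conditions has a replicate check. The genome-wide background recovered from the peak lists was 1.77 fragments per base for EBF1 in DMSO and 1.65 after dTAG-13, both on the scale to which peak calling had reduced these libraries. For Brg1 it was 0.607 in DMSO and 2.14 after dTAG-13, which made the dTAG-13 Brg1 library 3.54 times as deep by this measure.

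**Figure D1:**
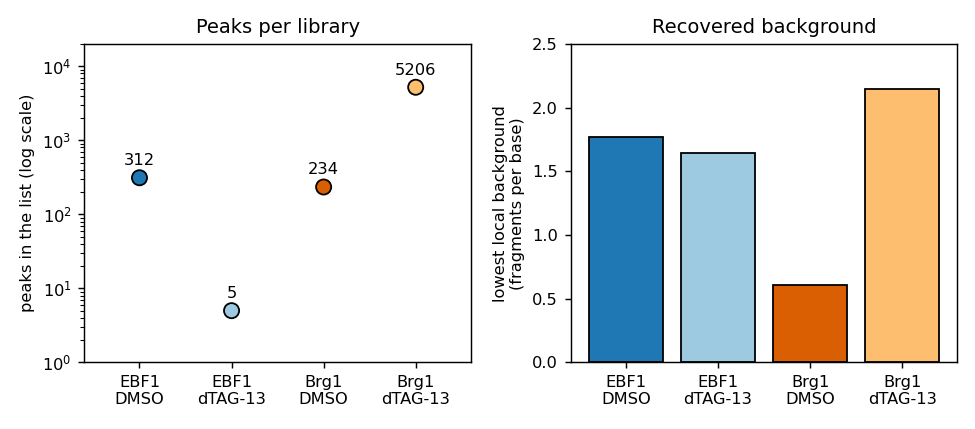
Peaks in each of the 4 lists (left, log scale) and the lowest local background recovered from each list in fragments per base (right, bars from 0, EBF1 on its scaled-down scale), with 1 library per group. EBF1 had 312 peaks in DMSO and 5 after dTAG-13, and Brg1 had 234 and 5206 at backgrounds that differed by 3.54 times.

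The first comparison asked how much EBF1 binding was left after 6 h of dTAG-13. EBF1 had 312 peaks in DMSO and 5 after dTAG-13, a ratio of 62.4. Of the DMSO peaks, 5 of 312 (1.60%, 95% interval 0.522 to 3.7%) were found again. None of the 15 highest EBF1 peaks and none of the 8 EBF1 sites assigned to early B-lineage genes was in the dTAG-13 list. Of these sites, some lay inside Pax5 (the B-lineage commitment factor) and Ebf1 itself, and within 1 kb of Igll1 (surrogate light chain), Vpreb3 and Cd79b (the Ig-beta chain of the B-cell receptor). The others were assigned by nearest gene to Cd72 at 2165 bp, Vpreb2 at 9761 bp and Foxo1 at 93840 bp.

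The highest EBF1 peak in DMSO lay at chromosome 18, 10918294 to 10918760, between genes and 99.9 kb from Mib1, a ubiquitin ligase of Notch signalling, with 90 fragments at the summit. The next were 22.2 kb from Cux1, a homeodomain factor (chromosome 5, 136589471 to 136590107, 75 fragments), 9.15 kb from Tbc1d16 (82 fragments) and 47.4 kb from Myl10, a myosin light chain (74 fragments). Slc25a26, the mitochondrial carrier of S-adenosylmethionine, and Sh2b3, an adaptor that restrains cytokine signalling, held the fifth and the eighth peaks within their bodies. Other leading peaks were assigned to Sh3gl3, Med13l, Actb, Adap1, Arap1, Bahcc1 and Irgc1. The tenth peak, at chromosome 6, 68884184 to 68884531, lay in the immunoglobulin kappa locus with no protein-coding gene within 100 kb. By the authors' fold enrichment, the median EBF1 peak in DMSO stood 6.68 times over background and the highest 26.2 times.

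EBF1 peaks in DMSO were placed near genes of the B lineage. Early B-lineage genes had a peak at 8 of 25 members against 0.32 in random lists, and the adjusted permutation p was 0.000333. The highest within it were Igll1 (chromosome 16, 16863978 to 16864365, 262 bp from the gene, 45 fragments), Pax5 (chromosome 4, 44706067 to 44706334, within the gene, 35 fragments) and Cd79b (chromosome 11, 106314497 to 106314696, 60 bp from the gene, 30 fragments). B-lineage transcription factors had peaks at 6 of 27 members (Pax5, Ebf1, Foxo1, Erg, Id3 and Mef2d) against 0.537 in random lists. Pre-B cell receptor signalling had them at 6 of 25 (Plcg2, Pik3cd, Pik3ap1, Inpp5d, Bank1 and Cd79b) against 0.43, and both lists gave an adjusted permutation p of 0.000333. The unadjusted p behind these 3 values, 0.0001, is the smallest that 10000 random lists can give. The other lists did not pass: proliferation and survival 1 of 28 (Bcl2l1), BAF subunits 1 of 25 (Actb), stress and heat shock 1 of 20 (Hspa1b) and erythroid and megakaryocyte genes 1 of 16 (Zfpm1). T-cell, myeloid and neuronal genes had 0 members with an EBF1 peak, of 21, 20 and 20.

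EBF1 summits in DMSO lay within 1 kb of a gene bound in 47 of 312 cases (15.1%, 11.3 to 19.5%), against 3.31% of random positions. A further 40.4% lay inside genes, close to the 39.8% of random positions, and 44.6% between genes. The 5 sites that were left after dTAG-13 were all within 1 kb of a gene bound, against 42 of the other 307, a comparison chosen after these sites had been seen. They lay at Hdlbp (vigilin, an RNA-binding protein), Kcnn1 (a calcium-activated potassium channel), Mphosph8 (a subunit of the HUSH silencing complex), Rtca (an RNA 3′-phosphate cyclase) and Pold4 (a subunit of DNA polymerase delta). At Hdlbp, chromosome 1, 93478212 to 93478505, the authors' fold enrichment was 11.6 in DMSO and 9.25 after dTAG-13. At Rtca, chromosome 3, 116508075 to 116508288, it was 5.55 in DMSO and 13.4 after dTAG-13, each against its own library's background and so not comparable in size. In the DMSO list the 5 sites ranked 16, 18, 98, 154 and 247 of 312, in the order Hdlbp, Kcnn1, Mphosph8, Rtca and Pold4. With only peaks of −log10 q of at least 10, the EBF1 ratio was 31.5, from 126 peaks in DMSO and 4 after dTAG-13.

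**Figure D2:**
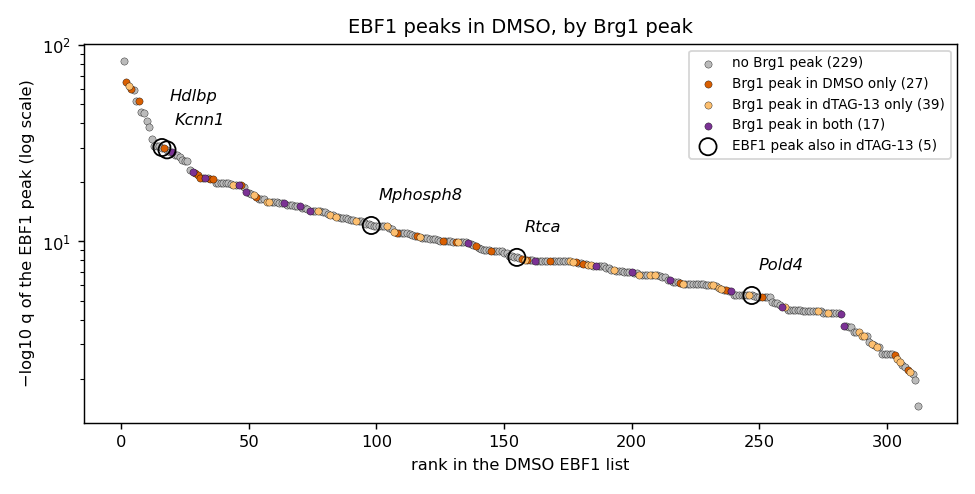
The 312 EBF1 peaks of the DMSO library by rank (horizontal) and −log10 q (vertical, log scale), coloured by the Brg1 list in which an overlapping peak was found. Rings mark the 5 sites also in the EBF1 dTAG-13 list, which are spread from rank 16 to rank 247.

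The next comparison asked where Brg1 was found in the EBF1-dTAG_N line with and without dTAG-13. EBF1 itself was mapped only in the EBF1-dTAG_C line, so its loss in the line used for Brg1 was not measured here. Brg1 had 234 peaks in DMSO and 5206 after dTAG-13, a ratio of 22.2. The peaks of DMSO were found again after dTAG-13 in 127 of 234 cases (54.3%, 47.7 to 60.8%), among them those assigned to Pax5, Cd79a, Blnk, Igll1, Lyn and Syk. Random placement gave 0.329 such overlaps. The share was 15% (35 of 234) under a reciprocal overlap of 50% and 20.1% (47 of 234) with the dTAG-13 list shortened to the DMSO length, but 49.1% (115 of 234) for summits within 250 bp. Peak width enters the reciprocal rule, since the median DMSO peak among the 127 was 218 bp wide and the dTAG-13 peaks over them 581 bp. For 74 of the 127 (58.3%, 49.2 to 67%), a count made after the data had been seen, the widths alone ruled out a reciprocal overlap of 50%. After dTAG-13, 5080 of the 5206 peaks were not in the DMSO list, and those that were stood at a median percentile of 85.9 of the dTAG-13 list. Thinning the dTAG-13 fragments to the DMSO background left a median of 768 peaks (726 to 818 over 100 draws). These had to pass the lowest −log10 p of the DMSO list, 5.89, whereas the dTAG-13 list reached down to 4.31. The ratio of the lists was 8.94 for peaks with a −log10 q of at least 10 and 7.86 for a fold enrichment of at least 5.

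The highest Brg1 peak after dTAG-13 was 26.3 kb from Sfi1, and the next were inside Nr2c2, 35.1 kb from Atp1b3, inside Pax5 (chromosome 4, 44670945 to 44671650, 52 fragments) and inside Tlr4, a receptor for lipopolysaccharide. They were followed by peaks inside Arhgef2, Plekha2 and Bank1, peaks outside but assigned to Kctd12, Mdfic, Chst3, Cmip, Lyn and Slc22a28, and an interval at chromosome 3 (100318303 to 100319023) without a gene in 100 kb. Lyn is a Src-family kinase of the B-cell receptor and Bank1 an adaptor in the same pathway. In DMSO, all 15 of the highest Brg1 peaks were high-background peaks. These numbered 34 of 234 (14.5%), with local backgrounds 17.3 to 198 times the lowest in the list, and 17 of them lay between 3000251 and 3035198 on chromosome 9. The named ones among the 15 were assigned to Rpusd4, Chl1 and Ly6c2. Of the 34, 2 were found after dTAG-13, and of the remaining 200 DMSO peaks 125 were (62.5%, 55.4 to 69.2%).

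Brg1 peaks were also assigned to B-lineage genes more often than random lists gave in both conditions. In DMSO, 7 of 25 early B-lineage genes had a peak, among them Cd79a, Vpreb2, Igll1, Pax5, Blnk and Foxo1, with an adjusted permutation p of 0.000333. Pre-B cell receptor signalling had 8 of 25 (Syk, Lyn, Blnk, Plcg2, Pik3ap1, Ptpn6, Bank1 and Cd79a; adjusted permutation p 0.000333), and B-lineage transcription factors 4 of 27 (Pax5, Foxo1, Erg and Id3; 0.0036). Myeloid genes passed with 2 of 20, Tlr4 and Csf2ra (adjusted permutation p 0.0233). Proliferation and survival had 2 of 28, Pim1 and Flt3 (adjusted permutation p 0.0579), which became 0.0406 within 20 kb, 0.0446 without matching and 0.0476 by the nearest bound. T-cell genes had 1 of 21 (Il2ra), and BAF subunits, stress genes, erythroid genes and neuronal genes had 0 in DMSO.

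After dTAG-13, 19 of 25 early B-lineage genes, 22 of 27 B-lineage transcription factors, 23 of 25 pre-B cell receptor genes and 20 of 28 proliferation and survival genes had a Brg1 peak. All 4 lists gave an adjusted permutation p of 0.000333. Examples were Ets1, Mef2c and Pou2f2 among the factors, Syk, Fcgr2b and Btk among the signalling genes, and Mcl1, Cdk6 and Socs2 among the proliferation and survival genes. Stress and heat shock genes passed with 7 of 20 (Hsp90ab1, Atf3, Atf4, Fosb, Jun, Jund and Ier2; adjusted permutation p 0.00382). T-cell genes passed with 8 of 21, among them Cd3d, Lck, Zap70, Il2ra, Lat and Id2 (0.008), although within 20 kb the adjusted permutation p was 0.0519. BAF subunits had 6 of 25 (0.196), myeloid genes 5 of 20 (0.158), erythroid genes 1 of 16 and neuronal genes 0 of 20, where random lists held 2.95. Whether a list differed between the conditions was not tested, because the lists differ in length and depth.

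**Figure D3:**
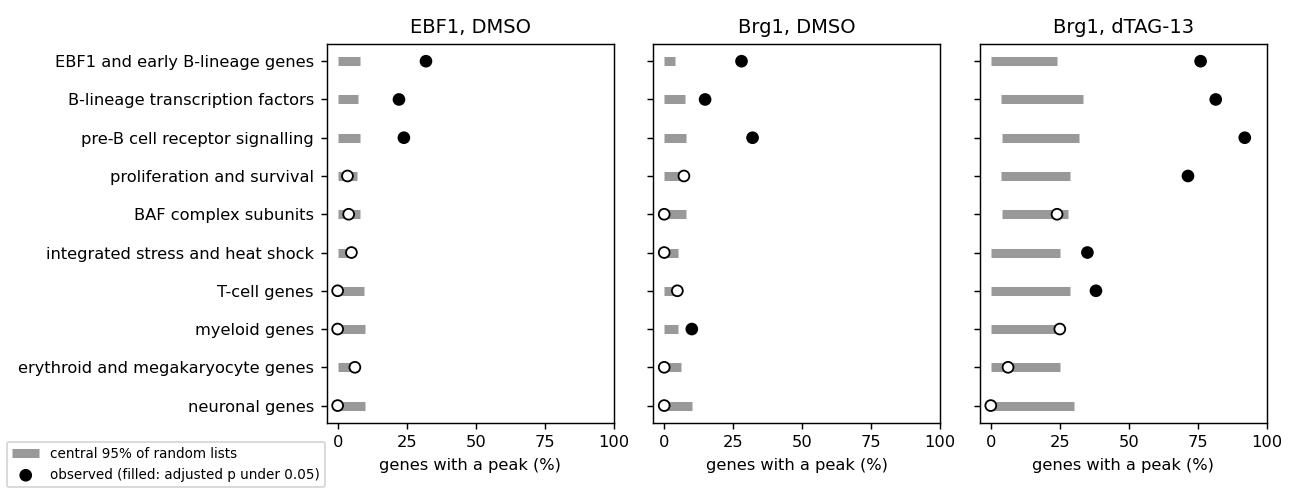
Percent of the members of each of the 10 gene lists with an assigned peak (points, filled where the adjusted p is under 0.05), in 3 peak lists, beside the central 95% of random lists (grey bars). The B-lineage lists lie to the right of the grey bars in all 3 panels, with 8 of 25, 7 of 25 and 19 of 25 early B-lineage genes.

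Brg1 peaks lay at gene ends in a larger share of the dTAG-13 list than of the DMSO list. In DMSO, 4.37% of Brg1 summits (2.11 to 7.88%) lay within 1 kb of a gene bound, near the 3.18% of random positions, and 59.4% lay between genes. After dTAG-13, 18.6% (17.5 to 19.7%) lay within 1 kb of a gene bound. Peaks of the dTAG-13 list alone gave 18.9%, and DMSO peaks found in both conditions gave 4.72%. The dTAG-13 peaks found in DMSO stood high in their list, at a median percentile of 85.9. The dTAG-13 library had 3.54 times the background of the DMSO one, so a shift of Brg1 to gene ends cannot be told apart from depth here. Among the gene-end peaks of fixed-list members were those at Myc (390 bp from the gene), Jun, Ier2 and Hsp90ab1.

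The design also allows EBF1 sites to be compared with Brg1, although the lists come from different cell lines. In DMSO, 44 of 312 EBF1 sites (14.1%, 10.4 to 18.5%) had a Brg1 peak, against 0.0162 in random placements. After dTAG-13, 56 sites (17.9%, 13.8 to 22.7%) had one, against 0.44. Both gave a permutation p of 0.0001, the smallest that 10000 placements can give, also when peaks were shifted by 10 to 100 kb (0.0895 and 2.07 overlaps). Neither placement was matched on open chromatin, so these p-values cannot tell a specific link of EBF1 with Brg1 from shared open chromatin. Which condition had more EBF1 sites with a Brg1 peak turned with the setting, with 40 in DMSO and 24 after dTAG-13 under a reciprocal overlap of 50%. It was 32 and 23 at a −log10 q of at least 5, and 44 and 5 with the dTAG-13 list shortened to the DMSO length. With all peaks, Brg1 was found in both conditions at 17 sites, in DMSO only at 27, after dTAG-13 only at 39, and in neither at 229.

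Sites with Brg1 in both conditions included those near Igll1, Ppp2r5a, Parp1, Dab2ip, Capn13, Kmt2e, Dnah1 and Zbtb18 and an interval in the kappa locus (chromosome 6, 70041023 to 70041223). Sites with Brg1 in DMSO only included 3 of the highest EBF1 peaks, those near Cux1, Myl10 and Med13l, a Mediator subunit. They were followed by Col26a1, Msi2 (an RNA-binding protein), Wdhd1, Snx5, Asb2, Car2 (carbonic anhydrase) and Iqsec1. The nearest Brg1 peak of the dTAG-13 list was 21.5 kb from the site near Cux1 and 119 kb from that near Med13l, but 42 bp from that near Myl10, and it was within 1 kb at 3 of the 27 sites. Sites with Brg1 after dTAG-13 only lay near Tbc1d16, Scd1, Txnrd3, Rinl, Tspoap1, Lrrk2, Cd79b and Endod1, and at chromosome 15, 63658117 to 63658344, and chromosome 6, 70493986 to 70494266. Of the 8 early B-lineage EBF1 sites, those assigned to Igll1 and Foxo1 had Brg1 in both conditions, the one assigned to Vpreb2 in DMSO only and the one assigned to Cd79b after dTAG-13 only. The remaining 4, assigned to Pax5, Ebf1, Vpreb3 and Cd72, overlapped no Brg1 peak. None of the 5 EBF1 sites left after dTAG-13 overlapped one either.

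Among Brg1 peaks, 44 of 234 in DMSO (18.8%, 14 to 24.4%) and 57 of 5206 after dTAG-13 (1.09%, 0.83 to 1.42%) were at EBF1 sites. Among the 234 highest peaks of the dTAG-13 list, 5 were (2.14%). Brg1 peaks at EBF1 sites in DMSO, which included those near Igll1, Foxo1, Cux1 and Myl10, were found again after dTAG-13 in 17 of 44 cases (38.6%, 24.4 to 54.5%). Brg1 peaks elsewhere, which included those assigned to Lyn, Syk and Erg, were found again in 110 of 190 (57.9%, 50.5 to 65%), an odds ratio of 0.458 (Fisher's exact test, p = 0.0284). The peak assigned to Erg was not among those found again. Without the high-background peaks, a comparison chosen after the data had been seen, 108 of the 156 peaks elsewhere were found again (69.2%), and the odds ratio was 0.28 (Fisher's exact test, p = 0.000355). The odds ratio was 0.591 (p = 0.135) for summits within 250 bp and 0.499 (p = 0.0727) without chromosome 5, the latter also chosen after the data had been seen, both by Fisher's exact test. Under a reciprocal overlap of 50% the direction turned, with an odds ratio of 1.55 (Fisher's exact test, p = 0.334). Widths alone ruled out such an overlap for 6 of the 17 peaks found again at EBF1 sites and 68 of the 110 elsewhere.

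**Figure D4:**
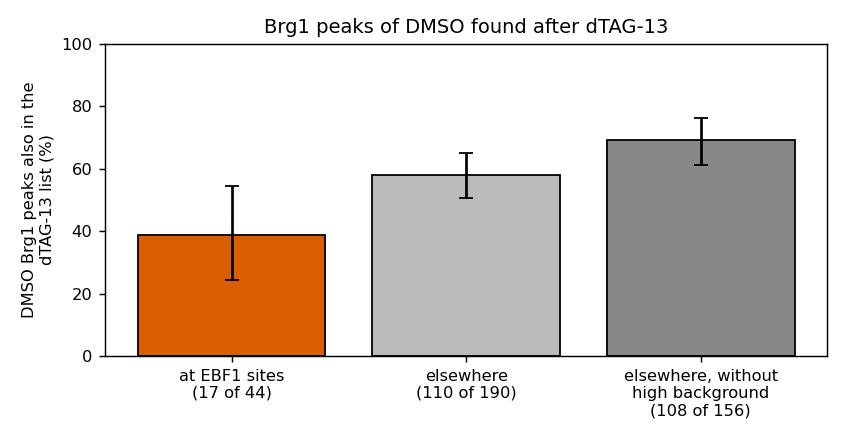
Percent of DMSO Brg1 peaks also found in the dTAG-13 Brg1 list, for peaks at EBF1 sites, elsewhere, and elsewhere without high-background peaks, with exact 95% intervals as error bars (counting error only). At EBF1 sites 17 of 44 were found again, against 110 of 190 elsewhere.

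The densest group of EBF1 peaks lay on chromosome 5, where 7 summits fell within 500 kb around Cux1, Myl10 and Col26a1. The same stretch held 3 Brg1 peaks in DMSO, each at an EBF1 site, and 9 Brg1 peaks after dTAG-13, with 0 at an EBF1 site. No EBF1 peak of the dTAG-13 list lay there. Chromosome 5 as a whole held 40 of the 312 EBF1 peaks (12.8%), with 5.64% of the length of the placed chromosomes. It was not alone in this, since chromosome 17 held 25 (8.01%, with 3.52% of the length) and chromosome 11 held 27 (8.65%, with 4.53%). Others fell below their share, such as chromosome 13 with 4 (1.28%, with 4.34%).

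**Figure D5:**
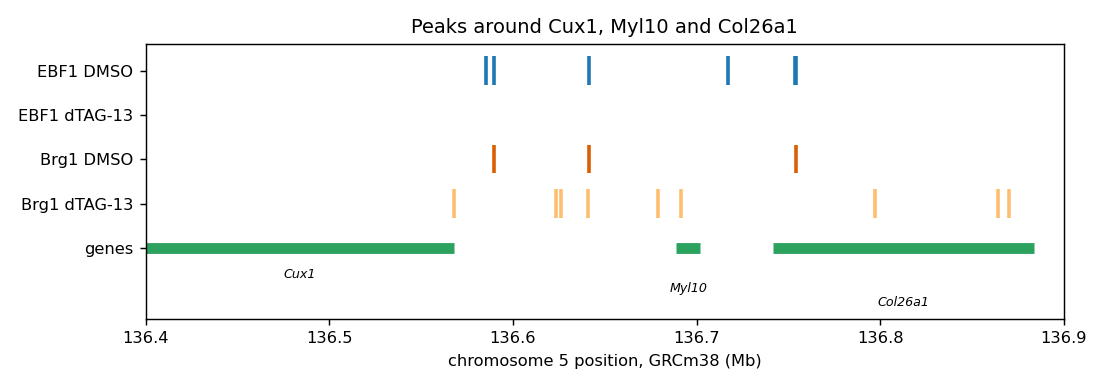
Map of the region around Cux1, Myl10 and Col26a1, chromosome 5 from 136.4 to 136.9 Mb (GRCm38), with the peaks of the 4 lists as vertical marks and protein-coding genes as bars, green for Cux1, Myl10 and Col26a1. It shows only part of the group of 7. Brg1 marks in DMSO stand at 3 of the EBF1 peaks, and the Brg1 marks of the dTAG-13 list lie outside the EBF1 peaks, the nearest 42 bp from the one near Myl10.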

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

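Tests that were chosen only after the result was seen are the depth test for the absent Brg1 peaks, the correction for selected summits, every comparison without high-background peaks or without chromosome 5, the count of overlaps ruled out by width, and the 3 tests on the remaining EBF1 sites. EBF1 and Brg1 peak counts moved in opposite directions under the same treatment. The log2 ratio of peak counts, dTAG-13 over DMSO, was -5.96 for EBF1 (312 to 5) and 4.48 for Brg1 (234 to 5206). This difference was not tested, since each value rests on 1 library per condition and on different cell lines and antibodies.

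The longer Brg1 list after dTAG-13 came from a library with 3.54 times the background. Thinned to the DMSO background, 768 of its 5206 peaks were left at the lowest −log10 p of the DMSO list, above the limit of 351 set for depth alone. That cutoff was 5.89, stricter than the 4.31 down to which the dTAG-13 list reached. The count was 796 (744 to 846) when the selection of high summits was corrected for. That run also redrew the fragments from a Poisson distribution, which spreads more than thinning, so its higher count is not an effect of the correction alone. Depth may therefore account for most of the added peaks, but not for all of them. Of 24 peaks that passed in nearly every thinned draw, 15 were in the DMSO list (62.5%, 40.6 to 81.2%), so whether both libraries saw the same Brg1 sites cannot be told apart from a change of sites with so few peaks. A better enrichment in 1 immunoprecipitation and a response of Brg1 to dTAG-13 both stay open, and the loss of EBF1 was not measured in this line.

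Brg1 peaks at EBF1 sites, such as those near Cux1 and Med13l, were absent by the 1 bp overlap rule after dTAG-13 more often than other Brg1 peaks. Too little depth is argued against, since the dTAG-13 Brg1 library had 3.54 times the background of the DMSO one. Lower fold enrichment at EBF1 sites is argued against too. The odds ratio within tertiles of fold enrichment was 0.378 over all 234 peaks (permutation test, p = 0.00771). It was not even, since in the lowest tertile 2 of 4 peaks at EBF1 sites and 32 of 74 elsewhere were found again. The middle tertile had 8 of 15 against 45 of 63, and the highest 7 of 25 against 33 of 53. Without high-background peaks the odds ratio within tertiles was 0.31 (permutation test, p = 0.00189). The lowest to highest tertiles then held 7, 15 and 22 peaks at EBF1 sites. Fold enrichment did not track being found again, however. Peaks elsewhere were found again in 44 of 60, 37 of 51 and 27 of 45 cases in these tertiles, and peaks at EBF1 sites in 3 of 7, 8 of 15 and 6 of 22. Peaks that are weaker by another measure are therefore not argued against. A dependence of Brg1 on EBF1 binding is the hypothesis that the design names. Among EBF1 sites with Brg1 in DMSO, those without an overlapping Brg1 peak after dTAG-13 had a median EBF1 −log10 q of 10.1. Those with one had 9.83 (difference 0.27, permutation p = 0.878), which leaves the hypothesis open. The odds ratio turned to 1.55 under a reciprocal overlap of 50%, which widths alone ruled out at 6 of 17 peaks found again at EBF1 sites and 68 of 110 elsewhere, and no replicate shows how often peaks of this height recur.

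The 5 EBF1 sites that remained, at Hdlbp, Kcnn1, Mphosph8, Rtca and Pold4, were not the 5 strongest. Their median rank was 98 of 312, but Hdlbp and Kcnn1 ranked 16 and 18. A median over 5 such ranks cannot decide whether incomplete degradation kept these stronger sites. Mphosph8, Rtca and Pold4, at ranks 98, 154 and 247, were not among the strongest. Fewer fragments are argued against, since 127 DMSO peaks (120 to 137) would pass after thinning to the dTAG-13 background, at the lowest −log10 p of the dTAG-13 list. Summit fragments in DMSO and after dTAG-13 were 33 and 35 at Mphosph8, 31 and 42 at Rtca and 19 and 25 at Pold4. They were 52 and 44 at Hdlbp and 46 and 34 at Kcnn1, with library backgrounds before scaling at a ratio of 0.981. Signal thus did not fall at Mphosph8, Rtca and Pold4. These sites were picked because they passed after dTAG-13, and each condition had 1 library. Signal at gene ends that does not depend on EBF1 therefore cannot be told apart from residual binding. All 5 sites lay at gene ends, and 10.6% of the 47 EBF1 sites at gene ends remained (3.55 to 23.1%). That share does not decide, since gene ends bound by EBF1 would be lost under either explanation.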

How the results depend on the processing

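Settings without high-background peaks, without chromosome 5 and with the gene of the nearest bound were chosen after seeing the data. Of 57 alternatives for 15 results, 34 left the result on its side of the threshold or within its range, 19 moved a value, 2 weakened a test and 2 reversed one. Peak ratios moved to 31.5 (EBF1) and 8.94 (Brg1) at a −log10 q of at least 10, and to 7.86 (Brg1) at a fold of at least 5. The share of DMSO Brg1 peaks found again moved from 54.3% to 15% under reciprocal overlap of 50%, 36.2% at a −log10 q of at least 5, 20.1% with the dTAG-13 list shortened and 62.5% without high-background peaks. EBF1 sites with Brg1 after dTAG-13 moved from 17.9% to 7.69%, 9.06% and 1.60% under the first 3 of these, below the DMSO shares of 12.8%, 12.6% and 14.1%, and to 25% for intervals within 1 kb. Brg1 dTAG-13 peaks at EBF1 sites were 0.461% under reciprocal overlap and 1.81% within 1 kb. The odds ratio of Brg1 peaks at EBF1 sites being found again was 0.591 for summits within 250 bp, 0.499 without chromosome 5, and reversed to 1.55 under reciprocal overlap of 50%, or 1.35 when high-background peaks were also left out. Over all its alternatives its p ran by Fisher's exact test from 0.000355 to 0.483. Without high-background peaks the odds ratio was 0.393 for summits within 250 bp and 0.3 without chromosome 5. Shares within 2.5 kb of a gene bound, or 1 kb of any gene's, were 23.4% and 22.1% (EBF1 DMSO), 10.5% and 9.61% (Brg1 DMSO), and 26.9% and 25.6% (Brg1 dTAG-13), as these settings take in more positions. Widths alone, counted after seeing the data, ruled out a reciprocal overlap of 50% for 6 of 17 peaks found again at EBF1 sites and 68 of 110 elsewhere. For the weakened odds ratios the cause was not tested. Of the 30 gene-list tests 13 passed, and 13 to 14 under the alternatives, with 12 of the 13 shared within 20 kb and all 13 under the others. No paired analysis was possible because each group holds 1 library and the labels carry no replicate numbers. The motif alternatives were not run, since no genome sequence was used. The low depth of the DMSO Brg1 library limits which Brg1 sites that list can hold.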

Other observations

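The calculations in this part were chosen only after the results were seen, and no test was run on the loci. Immunoglobulin loci held more Brg1 peaks than an even spread gave in both conditions. After dTAG-13, the kappa locus (chromosome 6, 67555636 to 70726754) had 48, against 6.49 for an even spread over the chromosome, and the heavy-chain locus (chromosome 12, 113407535 to 116009954) had 45 against 5.71. The lambda locus (chromosome 16, 19061752 to 19260844) had 7 against 0.388. T-cell receptor loci differed among themselves, with 9 against 0.354 at the gamma locus on chromosome 13, 6 against 2.8 at the alpha and delta loci on chromosome 14, and 2 against 1.37 at the beta locus on chromosome 6. In DMSO, Brg1 had 4 peaks in the kappa locus against 0.382, 2 in the heavy-chain locus against 0.195 and 1 in the lambda locus against 0.0211. The T-cell receptor loci had 0 in DMSO, where an even spread gave at most 0.144. EBF1 had 4 peaks in the kappa locus in DMSO against 0.276 and 0 in the other antigen receptor loci.

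Chromosome X held few peaks in every list. EBF1 had 0 in DMSO, where an even spread by length gave 21.9, and Brg1 had 1 in DMSO against 16 and 28 after dTAG-13 against 363. Btk, the kinase mutated in X-linked agammaglobulinaemia, lay at one of those 28. With the fragments of every dTAG-13 Brg1 peak on the numbered chromosomes halved and the background left as it was, 961 of 5169 peaks passed, which by length gives 67.5 for chromosome X. For EBF1 in DMSO the same calculation gave 7.94, and for Brg1 in DMSO 4.36.

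EBF1 peaks lay close together more often than random placements gave. Of 311 EBF1 peaks of DMSO outside high background, 46 (14.8%, 11 to 19.2%) had another within 50 kb, against 4.76 in random placements, and the permutation p of 0.0005 is the smallest that 2000 placements can give. Brg1 in DMSO had 23 of 200 against 1.87, with the same permutation p. Besides the Cux1 stretch, groups of EBF1 peaks lay near Tha1 and Cyth1 on chromosome 11 and near Lemd2, Hmga1 and Pacsin1 on chromosome 17.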
